A study of Bacillus subtilis PY79 with 59 samples.

How the data were processed

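Hi-C was made with HindIII and ChIP-seq with antibodies against SMC, ScpA, ScpB, ParB or GFP, per the labels' protocols. Bowtie2 2.1.0 is named in the submitters' processing notes. The genome build, the read numbers of the Hi-C maps, their bin width and the method that balanced them are not given in the sources used here. The deposited Hi-C files hold a fraction of contacts per pair of bins: each is a symmetric matrix of 404 by 404 values whose rows sum to 1 within rounding, with the diagonal and the next bin to each side at 0. The exception is the pair of the first and last bin, adjacent on the circle, which holds 0.0395 to 0.0717 and lies outside every ridge and band. A bin of 10 kb was inferred from the 404 bins and the genome length. The deposited ChIP and input files hold a coverage signal, a whole number at each of 4033459 bases, not normalized. Coverage changed in steps of 51 bp, so the number of reads was estimated as summed coverage over 51. Because each map is scaled to the same row sums, a gain in 1 part of a map lowers the rest. Because ChIP values are relative to the median bin, a gain over many bins likewise lowers distant ratios. Where values are scaled by the mean, a strong local gain does so too.

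Groups, parS positions, minutes and doses were taken from the labels. A label gave the rifampicin dose of 1 sample in different units in different fields, and the value in µg per ml from its protocol was used. Positions are those of the files, with the origin at the ends of the coordinates. A table of gene names of another PY79 assembly was given; since the build of the files is not named, its coordinates were not used, no region was placed in a gene, and the comparison of RNA polymerase over gene groups and the alternatives without rRNA and tRNA genes were not run. Regions replaced genes in the naming rule: the 25 highest RpoC-GFP regions, of which the text gives 8, and the 10 highest SMC regions more than 20 kb from parS. Adjacent 1-kb bins at or above 50% of a region's highest bin were joined, and bins with low input were left out.

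The inter-arm share is the percent of contacts within 5 bins of the antidiagonal through parS, at separations from 200 kb to the genome length less 200 kb. For the front, maps were smoothed by 3 by 3 means. At each separation s the highest value with left and right distances differing by at most 0.5 s was divided by the median at that distance. A ridge was called above 1.5 times the same statistic in the map without IPTG, and followed from 200 kb with gaps of at most 3 bins. Arm distances are medians over the last 5 called separations. Rates are least squares slopes over induced times with a called front below 90% of the arm; leaving out times without a called front was settled after the data were examined. The ridge ratio is the slope of right on left distance through the origin. Trends were tested by exact permutation of pairings, two-sided, where 6 or more times entered, with Benjamini-Hochberg adjustment over 4 trends.

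ChIP enrichment is the bin mean over the library's median bin, divided by the same for the matched input, in bins of 10 kb. Intervals are 95% Clopper-Pearson intervals on IP among IP and input reads. They cover counting error only, since reads without molecular identifiers are not independent molecules. Distance classes are means of bins. Circular shifts were of at least 200 kb and describe these libraries. With 1 library per group no test between groups was made. Except where stated, these choices and the list of alternatives were fixed before the data were examined.

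Measures added after seeing the data were a front followed from 400 kb or with searches of 0.7 and 0.9 s, a band along a traced ridge, a ridge ratio over separations of 400 to 2000 kb without threshold, class medians, and a front with its control inside each map. For the last, a ridge was called where the statistic at parS lay above a percentile of the same statistic at pivots at least 500 kb from parS and its antipode, and the separation divided by 2 was its distance. It was first run with the 95th percentile and a search of 0.1 s, without and then with pairs of bins of a median at least 2 times expected over the 24 maps set to the expected value. Because the outcome turned on that replacement, percentiles of 90, 95 and 99 and searches of 0.05, 0.1, 0.2 and 0.5 s, with these pairs replaced or kept, were then all run, which made 24 settings. A front read from where the ridge stayed within a narrow angle was also tried and not carried further.

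The procedures were tested on simulated data. In 36 simulated maps of 404 bins with a ridge and 10% noise, the left front was recovered within 10 kb and the ridge ratio within 0.00906, and in 18 maps without a ridge none was called. The simulated ridges had a constant height above the threshold and a sharp end, and their control had the same distance decay. The accuracy for faint or fading ridges was therefore not tested. A simulated enrichment of a 10-kb bin at 5 sizes was recovered within 0.987%. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.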

Results

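Contacts along the chromosome and the binding of the SMC complex were measured in Bacillus subtilis PY79 growing in rich medium. The series holds 59 libraries: 24 Hi-C maps of DNA contacts, 21 ChIP-seq libraries and 14 input libraries of total DNA. ParB (Spo0J) binds the DNA site parS and recruits SMC, a ring-shaped ATPase that works with its partners ScpA and ScpB. Each parS strain kept a single parS, whose position the labels give in degrees from the replication origin, with negative degrees on the left arm. In the strains with parS at -1° and at +26° and inducible ParB, native ParB was deleted and GFP-ParB was made after addition of 1 mM IPTG, so that loading of SMC could be started at a known time. Strains with parS at +26°, -27°, -59°, -94°, -117° and -153° made ParB continuously. A strain with parS at -94° carried gfp-smc under IPTG control, and an rpoC-gfp strain reported on RNA polymerase.

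The coverage files corresponded to 1.55 to 2.55 M reads per input and 0.469 to 5.62 M reads per ChIP library, estimated from reads of 51 bp. Read numbers behind the Hi-C maps are unknown, because the maps hold shares of contacts. Each group had 1 library except the -1° strain at 20 min of IPTG, which had 2 Hi-C libraries. Differences between single libraries therefore have no replicate check, and the spread of those 2 libraries is the only replicate error. The labels do not say whether they came from separate cultures. Their maps differed by a median of 11.3% per pair of bins and had identical values in 12.2% of pairs, so they were treated as separate libraries.

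The first comparison asks how contacts between the chromosome arms develop once ParB is made. In the -1° strain, the share of all contacts lying along the line of arm-to-arm pairing through parS was 1.85% without IPTG. It was 2.26% at 15 min, 2.57% ± 0.132 (SD, n = 2) at 20 min, 3.07% at 25 min, 3.36% at 30 min, 3.68% at 35 min and 3.98% at 45 min. The share rose with time (Pearson's r = 0.980, exact permutation p = 0.000198, adjusted p = 0.000794; Spearman's rho = 1, exact p = 0.000397, adjusted p = 0.00159; 7 time points, two-sided, Benjamini-Hochberg over 4 trends). The p of r is the smallest that permutations of 7 time points can give. Without the 2 times farthest from the median, r was 0.996.

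In the strain with parS at +26°, the same symmetric band held 1.87% of contacts without IPTG, 1.98% at 15 min and 2.06% at 35 min. The share rose with time (r = 0.963, exact permutation p = 0.00139, adjusted p = 0.00139; rho = 1, exact p = 0.00278, adjusted p = 0.00278; 6 time points), and r was 0.9497 without the 2 farthest times. The ridge of this strain bent away from the symmetric band. In a band that followed the ridge of the continuous-ParB strain with the same parS, chosen after seeing the data, the share went from 1.17% without IPTG to 2.50% at 35 min (r = 0.979, exact permutation p = 0.00139; rho = 1, exact p = 0.00278; not part of the 4 trends), and r was 0.998 without the 2 farthest times.

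The front, the farthest point reached by a ridge of raised contacts, was followed on each arm. In the -1° strain no ridge was called without IPTG. At 15 min the front stood 430 kb from parS on the left arm and 490 kb on the right. At 20 min it stood at 650 kb ± 70.7 on the left and 605 kb ± 91.9 on the right (SD, n = 2). At 25 min the distances were 960 and 1080 kb, at 30 min 1180 and 1190 kb, and at 35 min 1280 and 1340 kb. At 45 min the front was at 1660 kb on both arms, in a chromosome of 4033 kb. Its rate was 40.8 ± 2.83 kb per min on the left arm and 40.1 ± 4.55 kb per min on the right arm (slope ± SE, 6 time points). Distance rose with time on both arms (r = 0.991 and 0.975, exact permutation p = 0.00139, adjusted p = 0.00139; rho = 1, exact p = 0.00278, adjusted p = 0.00278). The rates differed by less than either standard error. Both distances are parts of the same called separation, and the search limits their difference, so the 2 arms are not independent measurements. A threshold of 2 instead of 1.5 called a front at 4 of the time points only and gave 7.2 and 2.51 kb per min.

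**Figure D1:**
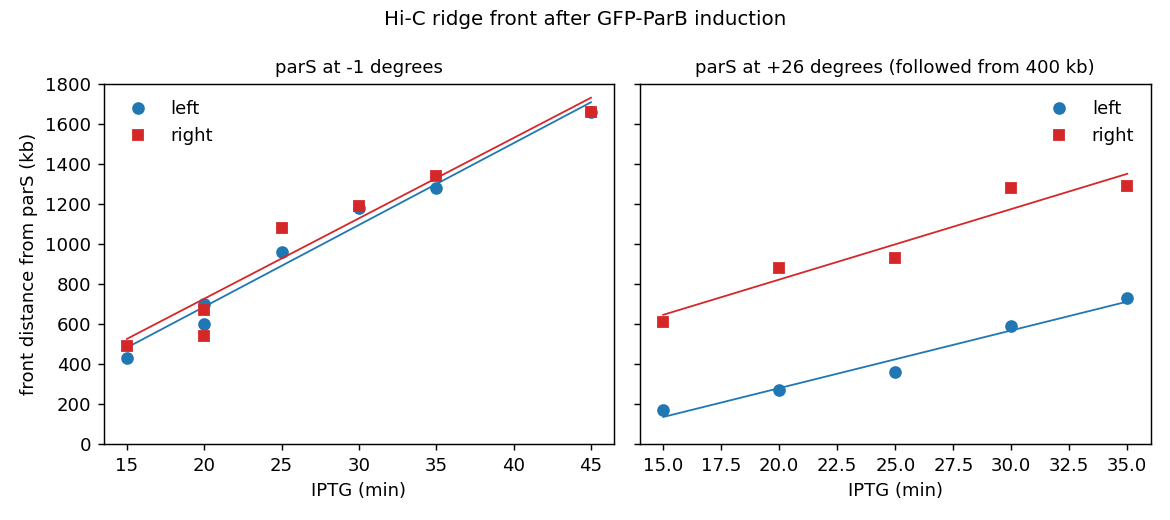
Distance of the Hi-C ridge front from parS (kb) against minutes of IPTG, with 1 point per library and lines fitted by least squares. Left panel: parS at -1°, where both arms reach 1660 kb at 45 min. Right panel: parS at +26°, followed from 400 kb of separation, where the right front lies farther from parS than the left at all 5 times.

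In the inducible +26° strain, left points toward the origin and right toward the terminus. At the threshold of 1.5, a front was called only at 30 min (610 kb left, 1280 kb right) and at 35 min (810 kb left, 1430 kb right). The slopes over those 2 times were 40 kb per min to the left and 30 kb per min to the right, with no standard error. With the lower threshold, a front was called at all 5 times and the order of the sides turned, at 36.6 ± 2.48 kb per min to the left and 45.4 ± 2.25 to the right. The times without a called front were left out; entered as 0 kb they gave 44.6 and 82.8 kb per min, a version added after seeing the data. Near the diagonal the ridge lay below the threshold, so the front was also followed from 400 kb of separation with a wider search, a setting chosen after seeing the data. The distances were then 170 kb left and 610 kb right at 15 min, 270 and 880 kb at 20 min, 360 and 930 kb at 25 min, 590 and 1280 kb at 30 min, and 730 and 1290 kb at 35 min. The slopes were 28.8 ± 2.87 kb per min to the left and 35.2 ± 5.67 kb per min to the right (slope ± SE, 5 time points, too few for a correlation). Leaving out each time in turn gave 27 to 32.2 kb per min on the left and 31.6 to 41.2 kb per min on the right, and the narrower search from the same start, also chosen afterwards, gave 31 and 43.6. Followed in the same way, the -1° strain gave 29.1 ± 7.37 kb per min on the left arm and 30.6 ± 6.80 on the right, with 1240 and 1360 kb at 45 min. Leaving out each time gave 23.0 to 45.6 and 26.4 to 42.5 kb per min, the highest without 45 min. From 200 kb with the wider search, the right slope at +26° was 2 kb per min over 2 times.

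Rifampicin, an inhibitor of RNA polymerase, was added at 25 µg per ml to ask whether the front moves without transcription. After 20 min of IPTG and 15 min more, the front of the -1° strain stood at 1190 kb on the left arm and 1220 kb on the right. With rifampicin in the last 15 min it was called at 90 and 130 kb, under the positions of both 20 min libraries, and the mean over both arms was -1.095 Mb relative to the map without rifampicin. At separations of 400 to 2000 kb the median of the highest contacts with rifampicin was 1.51 times the expected contact, against 2.81 times without rifampicin and 1.26 times in the map without IPTG. The called front compares the map with an untreated map, and the sign of the difference did not hold when other points of the same map served as control. In 24 settings of that control, all chosen after seeing the data, the front was longer with rifampicin in 11 and shorter in 13, from -0.645 to 0.38 Mb. The settings reuse 1 map per condition, so these counts are not independent. The sign turned on the raised pairs of bins: at the 95th percentile and a search of 0.1 s, it was 0.155 Mb with them replaced and -0.645 with them kept. In the latter setting the front with rifampicin stopped at 675 kb, as did both 20 min libraries.

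With ParB made continuously, the ridge left each parS unevenly, and the longer reach was on the side of the terminus in all 6 strains. The ratio of the distance toward the terminus to that toward the origin was 1.51 for parS at -27°, 1.63 at -59°, 1.71 at -94°, 1.70 at -117°, 1.501 at -153° and 1.96 at +26°. The median of the 6 was 1.67, and the ratio of right to left distance differed by an SD of 0.0417 between the 2 libraries of the -1° strain at 20 min. At a separation of 1000 kb, the -59° ridge paired a point 640 kb to the left of parS with a point 360 kb to its right, and with a wider search, chosen after seeing the data, the +26° ridge paired 230 kb left with 770 kb right. The ratio of 1.96 at +26° comes from a search in which no pair could exceed a ratio of 3; the wider search without a threshold gave a median of 2.92. The front on the terminus side was 1500 kb from parS at -27°, 1400 kb at -59°, 1000 kb at -94°, 780 kb at -117°, 450 kb at -153° and 1590 kb at +26°. Over separations of 400 to 2000 kb without a threshold, chosen after seeing the data, the -153° ratio was 1.21 with quartiles of 0.464 and 1.45. These values come from 1 map per strain.

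The course of the +26° ridge was compared without and with rifampicin. At the threshold of 1.5, a ridge was called in 1 of the 3 maps, the untreated one, so no ratio could be given for 10 or 30 min of rifampicin, where the lower threshold called 0 separations too. Over separations of 400 to 2000 kb without a threshold, a measure chosen after seeing the data, the median ratio of right to left distance was 2.92 in untreated cells (quartiles 2.36 and 3.25). It was 1.74 after 10 min (1.59 and 1.89) and 1.52 after 30 min of rifampicin (1.38 and 1.64). The same measure differed by an SD of 0.0229 between the 2 libraries of the -1° strain, and in that strain it was 0.989 without and 1.16 with rifampicin after 20 min of IPTG. The highest contacts had a median of 3.40 times expected in untreated +26° cells and 1.64 and 1.73 times after 10 and 30 min of rifampicin. Maps without IPTG gave ratios of 0.853 at -1°, at 1.26 times expected, and 3.59 at +26° (1.48 and 4.90), at 1.31 times. The lower ratios with rifampicin were read from fainter ridges. Whether faintness or a change of course lowered them was not tested.

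ParB ChIP checked the position of parS. ParB was enriched 243.8-fold over input in the 10-kb bin of the -59° parS (95% counting interval 237.3 to 250.7), 331.4-fold at -94° (322.3 to 340.8), 169.03-fold at -117° (163.1 to 175.2) and 152.4-fold at -153° (146.7 to 158.3). At the same positions the highest value in the strains with parS elsewhere was 0.998, 1.21, 1.44 and 1.13. The base of highest coverage was 3378459 in the -59° strain, 2983431 at -94°, 2728378 at -117° and 2313637 at -153°, on the coordinates of the files. Each lies within 6.04 kb of the position computed from the label's degrees. ParB fell with distance: in 1-kb bins 5 kb to the left and right of the peak it was 84.9 and 17.1 at -59°, 288.2 and 90.97 at -94°, 83.6 and 22.1 at -117°, and 25.9 and 60.1 at -153°. Over both sides of the 4 strains it was 2.35 to 11 at 20 kb and 0.528 to 3.59 at 50 kb. The median of the 4 strains was 206.4 in 10-kb bins, 536 in 1-kb bins and 348.8 in 5-kb bins. Scaled by the mean it was 121.1, and the strains lay closer together, at 125.2, 139.3, 116.6 and 116.9 for -59°, -94°, -117° and -153°.

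SMC was enriched at parS in each strain, and its mean at 200 to 500 kb lay above the median bin on both sides. In the parS bin it was enriched 6.03-fold at -59° (5.86 to 6.21), 14.3-fold at -94° (13.9 to 14.7), 22.3-fold at -117° (21.5 to 23.1) and 52.4-fold at -153° (50.4 to 54.4). The -94° strain with uninduced gfp-smc gave 13.3-fold (12.9 to 13.8). The highest value at these positions in the strains with parS elsewhere was 1.94, 6.36, 3.69 and 4.09 for -59°, -94°, -117° and -153°. At 200 to 500 kb from parS, mean enrichment on the left and right was 2.62 and 2.29 at -59°, 2.18 and 1.85 at -94°, 3.64 and 3.52 at -117°, and 2.57 and 1.54 at -153°. Scaled by the mean, chosen here after seeing the data, these ranged from 0.981, on the right at -153°, to 2.13. Single 50-kb bins centred within 500 kb of parS still fell below 1, to 0.752 on the left and 0.939 on the right at -153°. With uninduced gfp-smc they fell to 0.632 on the left and 0.820 on the right. At 500 to 1000 kb it was 1.85 on the left, toward the terminus, and 0.848 on the right at -94°, and 1.78 and 1.02 at -117°. At -153°, where that left range passes the terminus, it was 0.901 and 1.13. The median in the parS bin was 14.3 over the 5 libraries, and 60.1 with bins of 1 kb, where the highest bin inside the 10 kb was taken. With those bins the order of the strains changed: 17.4 at -59°, 60.1 and 73.03 at -94°, 40.1 at -117° and 85.2 at -153°. At that scale parS was not the highest SMC site at -59° and -117°. There, 2990001 to 2992000 reached 36.4 and 111.8. In the other libraries no region more than 20 kb from parS came as high as parS. Scaled by the mean, -117° gave 13.1 and -153° 33.4.

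**Figure D2:**
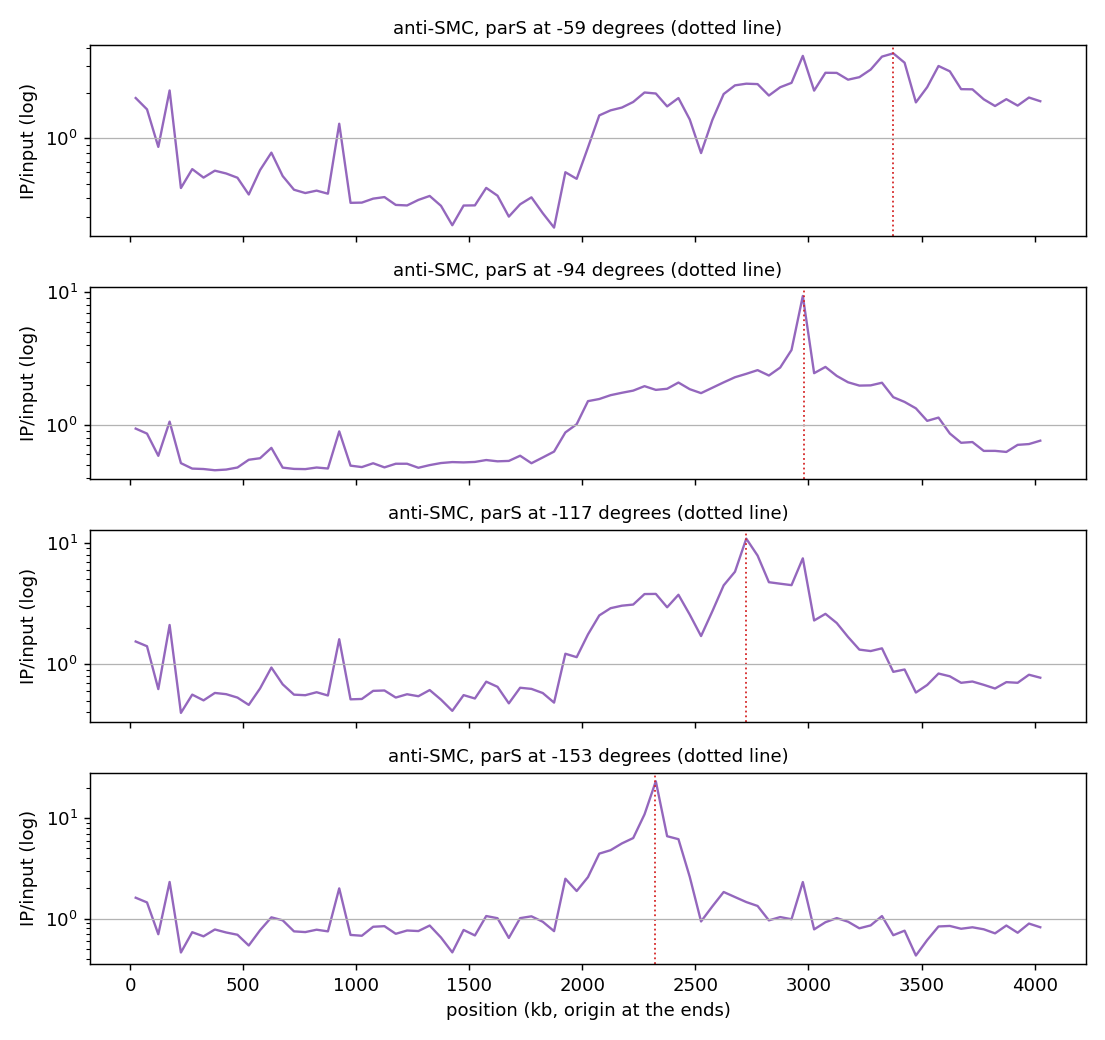
SMC enrichment over input (log axis, bins of 50 kb) against chromosome position (kb) in 4 strains, with the parS position as a dotted line. The highest bin holds parS in all 4 strains, at 3.67 against 3.53 in the next highest bin at -59°. In all 4 the signal falls on the left between 1970 and 2030 kb.

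The time course of SMC after ParB induction in the -1° strain asks whether SMC spreads outward from parS. In the parS bin, SMC enrichment was 1.74 without IPTG (1.69 to 1.79), 4.15 at 15 min (4.04 to 4.26), 5.35 at 20 min (5.21 to 5.48) and 5.28 at 25 min (5.14 to 5.42). At 200 to 500 kb, the ratio to 0 min was 1.84 on the left and 1.67 on the right at 15 min, 2.14 on both sides at 20 min, and 1.95 and 1.93 at 25 min. At 500 to 1000 kb, the ratios were 0.974 and 1.15 at 15 min, 1.22 and 1.43 at 20 min, and 1.47 and 1.53 at 25 min, the last being 1.005 and 1.05 when scaled by the mean. At 1000 to 2000 kb they were 0.819 on the left and 0.759 on the right at 25 min. In the parS bin the ratio of 25 min to 0 min was 3.03, and it was 5.48 with bins of 1 kb. With 4 time points no correlation is given.

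GFP-SMC was induced in the -94° strain, where ParB was present throughout. In the parS bin, anti-GFP enrichment was 3.06 without IPTG (2.91 to 3.21), 7.18 at 10 min (6.91 to 7.46), 23.2 at 15 min (22.4 to 24.0), 23.4 at 20 min (22.6 to 24.2) and 19.2 at 25 min (18.6 to 19.9). At 20 to 200 kb, the ratio to 0 min was 1.39 on the left and 1.07 on the right at 10 min, 3.67 and 2.53 at 15 min, 4.44 and 3.83 at 20 min, and 3.53 and 3.06 at 25 min. At 200 to 500 kb it was 0.929 and 0.905 at 10 min, 1.80 and 1.18 at 15 min, and 2.93 and 2.04 at 20 min. At 500 to 1000 kb, the left side, toward the terminus, went from 0.846 at 10 min to 1.53 at 25 min, or 1.01 when scaled by the mean, while the right side was 0.908 at 25 min. In the parS bin the ratio of 25 min to 0 min was 6.29, and it was 4.17 when scaled by the mean. The library without IPTG, which divides all these ratios, was the shallowest ChIP library, at 0.469 M reads. Depth rose along the course, to 0.727, 1.91, 2.23 and 3.24 M reads at 10, 15, 20 and 25 min.

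**Figure D3:**
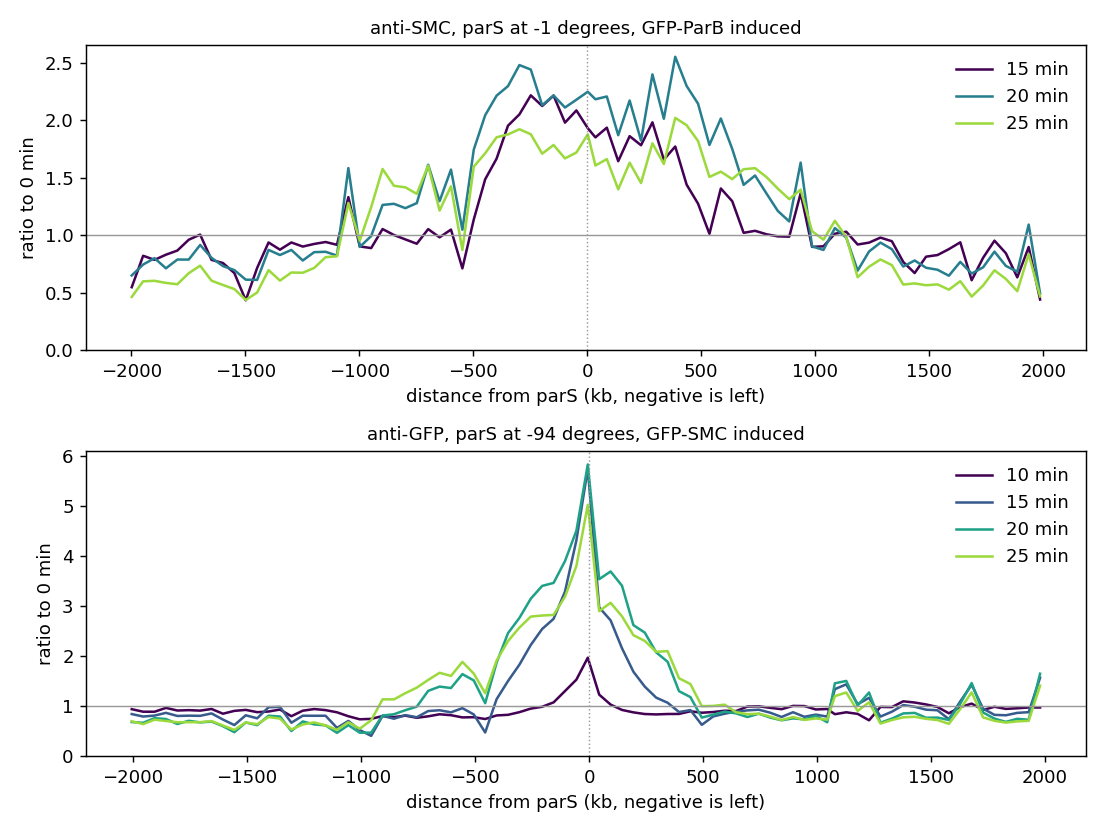
Enrichment relative to 0 min (bins of 50 kb) against distance from parS (kb, negative to the left) after induction of GFP-ParB in the -1° strain (top) and of GFP-SMC in the -94° strain (bottom), 1 line per time and 1 library each. The raised region is wider at 25 min than at 15 min in both panels.

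ScpA and ScpB, the partner subunits of SMC, were profiled in the -153° strain. In the parS bin ScpA was enriched 20.0-fold (19.3 to 20.8) and ScpB 25.1-fold (24.2 to 26.1). Across bins of 10 kb, SMC ranked with ScpA at rho = 0.809 and with ScpB at rho = 0.809, and both were 0.794 without the bins within 50 kb of parS. No circular shift of the profiles by 200 kb or more came as high, the highest being 0.227 and 0.253. ScpA and ScpB ranked with each other at 0.964, and SMC with ParB at 0.607. The libraries share 1 input, and bins are not replicates.

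SMC was also set against RNA polymerase. The highest RpoC-GFP regions were 914001 to 916000 (160.2-fold in its highest 1-kb bin), 512001 to 513000, 598001 to 601000 (125.2-fold), 2990001 to 2997000 (101.7-fold), 90001 to 101000 (99.5-fold), 161001 to 176000 (87.8-fold), 30001 to 35000 (87.1-fold) and 909001 to 913000 (84.9-fold). Across 1-kb bins, SMC, ScpA and ScpB enrichment, as a residual from a running median over 50 kb, ranked with RpoC-GFP at a median rho of 0.287 over 11 libraries (0.211 to 0.427). In 11 of 11 libraries rho lay above each of 3635 circular shifts. Of the 10 highest SMC regions more than 20 kb from parS, the number in the top 1% of RpoC-GFP bins was 4 in the -59° strain, 2 at -94°, 3 at -117° and 2 at -153°. It was 6 in the -94° strain with uninduced gfp-smc, and 8, 9, 5 and 6 in the -1° strain at 0, 15, 20 and 25 min. A region counts by its highest RpoC-GFP bin, so the number depends on how far bins were joined. In the -1° strain, 30001 to 35000 lay at percentile 99.7 at 15 min, and its part 34001 to 35000 at 98.8 at 20 min. Without division by input the median rho was 0.443. Neither bins nor regions are replicates, and the anti-GFP library without IPTG gave a rho of 0.283.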

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

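No test was run on the results of this part, and no biological explanation was tested. The input libraries served the comparisons only as divisors, and 2 signals appear in them. In the 5 inputs of the gfp-smc strain, 430 to 433 bases in 1 stretch at 328166 to 328598 had no reads, against 0 bases without reads there in the other 9 inputs; the highest count was 433. The labels place gfp-smc at amyE in this strain.

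The ratio of highest to lowest input coverage along the chromosome, in running means over 3 bins of 50 kb, was 4.04 in the rpoC-gfp strain. In the other 13 inputs it ran from 2.57 to 3.07. The lowest point lay at 2025 kb in the rpoC-gfp input. The rpoC-gfp input is 1 library, so this difference has no replicate check.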

How the results depend on the processing

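The tests with the control inside each map, other starts and searches, uncalled times as 0 kb, the traced ridge, 400 to 2000 kb, class medians and mean scaling of SMC classes by strain were chosen after the results were seen. The rise of the inter-arm share kept its direction and its side of the threshold in both strains under every alternative run. In the -1° strain r was 0.975 to 0.984 leaving out either 20 min library. Front rates there were 38.6 to 44.6 kb per min on the left and 37.7 to 45.7 on the right leaving out each time or library. A threshold of 2 gave 7.2 and 2.51, and the control inside each map gave 54.45, or 54.1 with raised pairs kept. At +26° the left rate, 40 in the main setting, was 15.2 with smoothing of 1 by 1 and 22, over 2 times, with 5 by 5. Its right rate was 82.8 with uncalled times as 0 kb and 2 from 200 kb with a search of 0.7 s.

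The rifampicin difference of the -1° strain, -1.095 Mb, was -0.905 with the lower threshold, -0.7 with 2 and -0.935 with smoothing of 1 by 1. With the control inside each map it depended on the replacement of raised pairs, the search and the percentile. With the pairs replaced it was 0.275, 0.38, 0.155 and 0.07 Mb for searches of 0.05, 0.1, 0.2 and 0.5 s at the 90th percentile, 0.27, 0.155, 0.145 and -0.015 at the 95th, and 0.155, 0.155, 0.165 and -0.105 at the 99th. With the pairs kept it was 0.275, -0.005, -0.645 and -0.38 at the 90th, -0.005, -0.645, -0.645 and -0.315 at the 95th, and -0.645, -0.645, -0.645 and -0.31 at the 99th. The median ridge ratio of 1.67 was 1.45 with the lower threshold, 1.85 with 2 (4 strains), 1.77 and 1.53 with smoothing of 1 by 1 and 5 by 5, 1.54 with the other strain's uninduced map and 1.79 over 400 to 2000 kb. Of the 3 maps at +26° with or without rifampicin, 0 had a ridge at a threshold of 2 and 3 gave a ratio without threshold.

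Without division by input, parS enrichment was 216.2 for ParB and 13.3 for SMC, and the 25 min to 0 min ratio was 2.77 for SMC. Bins of 1 kb gave 536, 60.1, 5.48 and, for GFP-SMC, 6.99; bins of 5 kb gave 348.8, 19.4, 4.38 and 7.25; scaling by the mean gave 121.1, 11.7, 2.08 and 4.17. Directions turned away from parS: scaled by the mean, SMC on the right fell to 0.981 at 200 to 500 kb at -153°, and at 500 to 1000 kb to 0.969 at -59°, 0.598 at -117°, 0.718 at -153° and 0.711 with uninduced gfp-smc. At 1000 to 2000 kb on the left the SMC ratio was 1.03 with bins of 1 kb, and on the right the GFP-SMC ratio was 0.977 without input, 0.680 scaled by the mean and 0.781 as a median. The rank correlation with RNA polymerase was 0.263 and 0.332 with running medians of 20 and 200 kb and 0.443 without input. Where no cause is given, the cause was not tested.

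Among further values of single strains and distance classes, 44 moved by less than the spread used, 70.1% by more, and 9 changed direction. Distance classes have no spread of their own, so the relative counting interval of the parS bin was used. RNA polymerase over gene groups and the setting without rRNA and tRNA genes were not run. No paired analysis was possible because each group but 1 had a single library. Read depth limits the ChIP intervals; the depth of the maps is unknown.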

Other observations

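Of the tests in this part, only that on the pixels around raised pairs was set before its result was seen; those on rifampicin, on the anti-GFP library, on enrichment in the top RpoC-GFP bins and on raised pairs with rifampicin, and the step and the peak below, were chosen after. In the profiled strains making ParB continuously, all with parS on the left arm (-59°, -94°, -117° and -153°), SMC, ScpA and ScpB enrichment fell on passing the terminus. The position that best split 10-kb bins between 1600 and 2300 kb into 2 levels was 1970 to 2050 kb in 7 libraries, with a median of 2030 kb. The level on the side of parS was 3.03 to 5.37 times that beyond. The window ends close to the -153° parS, at 2319 kb. In that strain the level on the side of parS therefore includes the flank of the parS peak, at 5.37 times for SMC, 4.15 for ScpA and 5.25 for ScpB. A split into 2 levels returns a position in any profile. Without division by input the positions were 1980 to 2050 kb. The -1° strain was left out of this range: its 4 libraries split at 2060 to 2110 kb, with levels of 0.610 and 0.805 at 0 min and 0.392 and 0.485 at 25 min. The Hi-C fronts toward the terminus ended at 2235 kb at -27°, 1975 at -59°, 1985 at -94°, 1945 at -117°, 1865 at -153° and 1885 at +26°.

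A narrow SMC peak stood at that step. In the 1-kb bin from 2033001 to 2034000, SMC enrichment was 5.84 at -59°, 8.90 at -94°, 12.8 at -117°, 24.0 at -153° and 5.15 in the -94° strain with uninduced gfp-smc, with medians of 1.12 to 3.19 in the higher of the 2 flanks of 30 kb. It was 2.14, 1.16, 1.08 and 1.29 in the -1° strain at 0, 15, 20 and 25 min, where that flank was 0.637, 0.352, 0.358 and 0.417. ScpA and ScpB in the -153° strain gave 2.91 and 3.92 (flanks 1.57 and 1.55). ParB lay between 0.619 and 1.94 (flanks 0.422 to 1.02), RpoC-GFP was 0.559 (0.738), and GFP-SMC in the -94° strain ran from 0.539 to 1.48 (0.423 to 0.703). Input coverage in this bin was 0.414 to 0.632 of the median bin.

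Short-range contacts differed with rifampicin: pairs 20 to 100 kb apart held 9.55%, 9.85% and 10.4% of contacts in the 3 rifampicin maps and 15.4% to 18.1% in the other maps. The front statistic is divided by the median at each distance, so a lower short-range share is not itself a fainter ridge. In the -1° strain the ridge was fainter too. Over the separations used without a threshold, its highest contacts had a median of 1.51 times expected with rifampicin and 2.81 times without. The front called near parS with rifampicin in the -1° strain may come from this lower ridge contrast against an untreated control map. In 18 of the 24 settings of the control inside each map, over 50% of separations from 2000 to 3000 kb lay above other pivots without rifampicin, and in 18 of those 18 the same held with rifampicin, at 90.1% or more, against 1.98% to 16.8% in the 20 min libraries. In the other 6, which searched 0.5 s, the map without rifampicin reached at most 11.9% and the map with it 0% to 32.7%. With rifampicin, contacts beyond the 20 min fronts were therefore raised in those 18 settings. A ridge that, followed from parS without a break, ends short of those fronts stays open. In the 20 settings with a front called in both 20 min libraries, that with rifampicin lay beyond both in 12 and below both in 1. In all 24 settings it lay at 675 to 1920 kb. None put it as near parS as the 90 and 130 kb called against the untreated map. Neither its end nor its rate can be given from 1 map.

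The fine-scale ranking of SMC with RNA polymerase could come from recovery of transcribed DNA without the target, and the tables do not decide. The anti-GFP library without IPTG gave a rho of 0.283, inside the range of 0.211 to 0.427 of the SMC, ScpA and ScpB libraries, but it was enriched 3.06-fold at parS, so leaky GFP-SMC stays open; ParB libraries gave 0.244 to 0.342. In the -1° course, median enrichment in the top 1% of RpoC-GFP bins was 19.3 at 0 min. It rose to 31.3, 44.9 and 43.4 at 15, 20 and 25 min of ParB induction. After GFP-SMC induction it went from 7.82 to 7.67, 15.2, 17.1 and 13.7 at 10, 15, 20 and 25 min. The rise argues against recovery without the target only as scaled by the median bin. From 0 to 20 min at -1°, median coverage per base fell from 18 to 10, while mean coverage went from 47.5 to 52.7. In the GFP-SMC course they went from 4 to 10 and from 5.93 to 28.2. The rise scaled by the mean was not computed. Median enrichment in those bins was 2.66 and 6.31 in the 2 SMC libraries with parS at -94°. Without replicates the rise has no spread to be held against. At -1° the rise in top regions near parS cannot be told apart from SMC spreading from parS. Top RpoC-GFP regions such as 30001 to 35000 and 161001 to 176000 lie 20 to 200 kb to its right. Mean SMC in that class, relative to 0 min, was 1.90, 2.11 and 1.73 on the right and 2.07, 2.02 and 1.81 on the left. The class holds those regions themselves, and its medians on the right were 1.89, 1.45 and 1.29. At 15 min, 50-kb bins with the farther top regions 914001 to 916000 and 2990001 to 2997000 were at 1.36 and 1.33. Their neighbours were at 0.898 to 0.986. The bin with 512001 to 513000 was at 1.01, between 1.27 and 1.41. With 1 library per time, these bins do not decide. A share of true SMC binding at the top RpoC-GFP regions was not tested and stays open too.

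In the 24 maps, a set of distant pairs of bins had a median of at least 2 times the expected contact. The highest joined 1990001 to 2000000 with 3370001 to 3380000, at 5.65 times expected (3.57 to 12.5). A local contact, which could raise nearby pixels too, was argued against: the 8 pixels around a pair had a median of 1.04 times expected, against 2.29 for the pairs, though 6.57% of the pairs had a neighbour at 2 or more, among them the highest pair, with 1 at 3.47. Dependence on transcription was argued against by a median of 2.35 in the 3 rifampicin maps and 2.35 in the other 21. The pairs had been chosen by their median over all 24 maps, the 3 with rifampicin among them. Reads shared between repeated sequences were not tested, since no genome was used here, and stay open.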
